A study of Homo sapiens with 2 samples.

How the data were processed

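Gene expression in MCF7 cells was measured by RNA sequencing in 1 untreated library and 1 library of cells kept in 10 nM eribulin for 2 days. Per the labels' protocols, total RNA was purified on a Qiagen column kit and libraries were built with the Illumina TruSeq Stranded mRNA kit, which selects polyadenylated transcripts. The deposited table gave, per the file headers, counts of total gene reads and RPKM values for each library. The counts were raw reads per gene, and the RPKM values were scaled by the authors for gene length and sequencing depth. The genome build was hg19 per the submitters' processing notes. The aligner, the counting program, the strand setting and which reads entered the RPKM were not given in the sources used here. The untreated library had 4253 genes with reads and an RPKM of 0, and the eribulin library 4915, so the RPKM values rest on fewer reads than the counts. Genes were identified by the symbols and Ensembl identifiers of the table, which held no coordinates. The annotation at hand was GENCODE release 29 on a later build than hg19, so no coordinates were printed. It served only for gene type, transcript length and GC content, and 52338 of the 57773 identifiers matched it.

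Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3), 0.929 for the untreated and 1.08 for the eribulin library. Genes with at least 1 CPM (counts scaled to a common number of gene reads per library) in at least 1 library were kept. The log2 ratio of eribulin over untreated used a prior count of 1 in proportion to the scaled library size. Its 95% interval came from the exact conditional binomial (Clopper-Pearson) of the raw counts in both libraries. With 1 library per group no test across genes was possible and no p-value was computed. A gene was called higher or lower by a fixed rule of size, a ratio of at least 2-fold with an interval excluding no change. PCR copies are not independent molecules, so intervals and floors cover counting error only. A gene without reads in a library was given a bound against a floor of 3 counts in that library, 0.159 CPM for untreated and 0.168 for eribulin. Fold values are ratios of TMM-scaled counts without the prior.

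For 35 gene lists the median log2 ratio was set against 10000 random lists of the same size drawn from the same 10 bins of mean expression. The named genes were 12 with high and 12 with low interval bounds nearest to 0 among those past the rule, 29 genes of antigen presentation, p53, tubulin and cell cycle biology, and up to 4 members per list with the largest absolute log2 ratio. From the naming of the 12, unnamed loci and symbols ending in P and a number, meant for pseudogenes, were left out, while clone-named loci stayed in. The symbol pattern also passed over the protein-coding genes GBP1 and GBP4, whose bounds lay above those of IFIT3 and PSMB9, and so the 12 are not strictly the highest. Examples outside this rule were chosen after their values were seen. They were ULBP1, ULBP2, ULBP3, MICA, MICB, MB21D1, the NFY genes, CALR, CANX, PDIA3, PTPRC, IFITM2, FAM72A, FAM72B and FAM72D. NFKBIA, NFKB1, NFKB2, SOD2, CD8A, TMEM173, IFI16, AIM2, TUBA1A, TUBA8, TUBB1, TUBG1, TUBG2, TUBD1 and TUBE1 were also such examples. In the closing observations they were WARS, IDO1, CXCL9, KLF2, CSPG4P9, CSPG4P10, the PIK3R2 entries, the interferon genes and members of gene families. The lists, the rule, the scaling and most alternatives were set before the data were examined. Symbols were matched as written, so TAP2, TUBB3 and NDUFB8, which carry suffixes in the table, were left out of their lists.

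The rule was tested on simulated counts with counting error only, for the 16021 kept genes with 200 genes changed. It called 97% of 4-fold and 95% of 2.83-fold changes and 0.354% of unchanged genes. The intervals held the simulated fold for 95.7% of genes. Variation between cultures or library preparations was not simulated, so these shares are not error rates for eribulin against untreated cells. Of 40 random lists of unchanged genes, 2.5% fell outside percentiles 2.5 to 97.5.

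The alternatives were DESeq2 1.42.0 size factors, total gene counts, the upper quartile, no filter on low counts, a minimum of 10 CPM, prior counts of 0.25 and 5, the ratio of the deposited RPKM values with 0.1 added, thresholds of 1.5-fold and 4-fold, and random lists not matched on expression. Random lists matched also on length and GC content, first with merged exon length and then with the length of the principal transcript, and lists with suffixed rows added were chosen after the data were seen. The measure of length was changed after the result with merged exon length was seen, because merged exons misstate short genes (a median of 3444 bases for ribosomal proteins against 803 by principal transcript), and both results are given. Bins of 4 lengths and 3 GC classes were used within each expression bin. Bins with too few other genes for a list were merged within their expression bin. Where that still left too few, the whole expression bin was used without regard to length or GC content. The denominators of the deposited RPKM values were recovered as the common divisor of reads over RPKM, 19129720 for untreated and 18275119 for eribulin. Of 14993 kept genes with an RPKM above 0 in both libraries, the reads behind the RPKM could be recovered as whole numbers within 1e-05 at a single gene length for 11328 (75.6%), 3664 were ambiguous and 1 had no solution. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.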

Results

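RNA sequencing measured gene expression in MCF7, a human breast cancer cell line that expresses the oestrogen receptor. Eribulin is a cancer drug that binds tubulin and blocks the growth of microtubules. Cells were left untreated (0 nM) or received 10 nM eribulin for 2 days, with 1 library per group. The table listed 57773 genes. The untreated library held 18845239 gene reads over 23062 genes, and the eribulin library 17883646 gene reads over 25330 genes. The 10 most abundant genes took 8.75% of the untreated reads and 7.65% of the eribulin reads. There was no replicate check, so every value describes these 2 libraries. The 95% intervals given below cover counting error only.

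The comparison of eribulin with untreated cells addressed whether the drug raises HLA class I, the molecules that display peptides to cytotoxic T cells, together with NLRC5, a transcriptional activator of the class I genes. NLRC5 (ENSG00000140853) had 1 read in the untreated library and 4204 in the eribulin library, a 3826-fold ratio (interval 686 to 151143). HLA-A, HLA-B and HLA-C were 22.2-fold, 268-fold and 112-fold higher in the eribulin library. Interferon-stimulated and HLA class II genes were higher as a block, and so were many targets of p53. Most genes of mitosis and DNA replication and 10 of 16 tubulin genes were lower in the eribulin library. Of 16021 genes measured at 1 CPM (counts scaled to library size) or more in at least 1 library, 2093 were at least 2-fold higher in the eribulin library with an interval excluding no change, 1322 were lower by the same rule and 12606 were neither. Higher genes made up 61.3% of those past the rule, but 46.6%, a minority, with a minimum of 10 CPM (711 higher and 815 lower). With scaling by total gene counts the split was 2729 higher and 936 lower, or 74.5% higher, and the median of all genes moved up by 0.21 on the log2 scale. At least 8-fold differences were held by 371 higher and 70 lower genes. Of the higher genes 86 had no reads in the untreated library, and of the lower genes 27 had none in the eribulin library.

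Of the 35 gene lists, 21 had a median log2 ratio outside the central 95% of random lists of equal size and matched expression, 15 above and 6 below. By chance 1.75 lists would be expected if genes varied independently. Members of a list can vary together and some lists share genes, so the true number may be larger. These percentiles describe the 2 libraries and are not p-values.

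**Figure D1:**
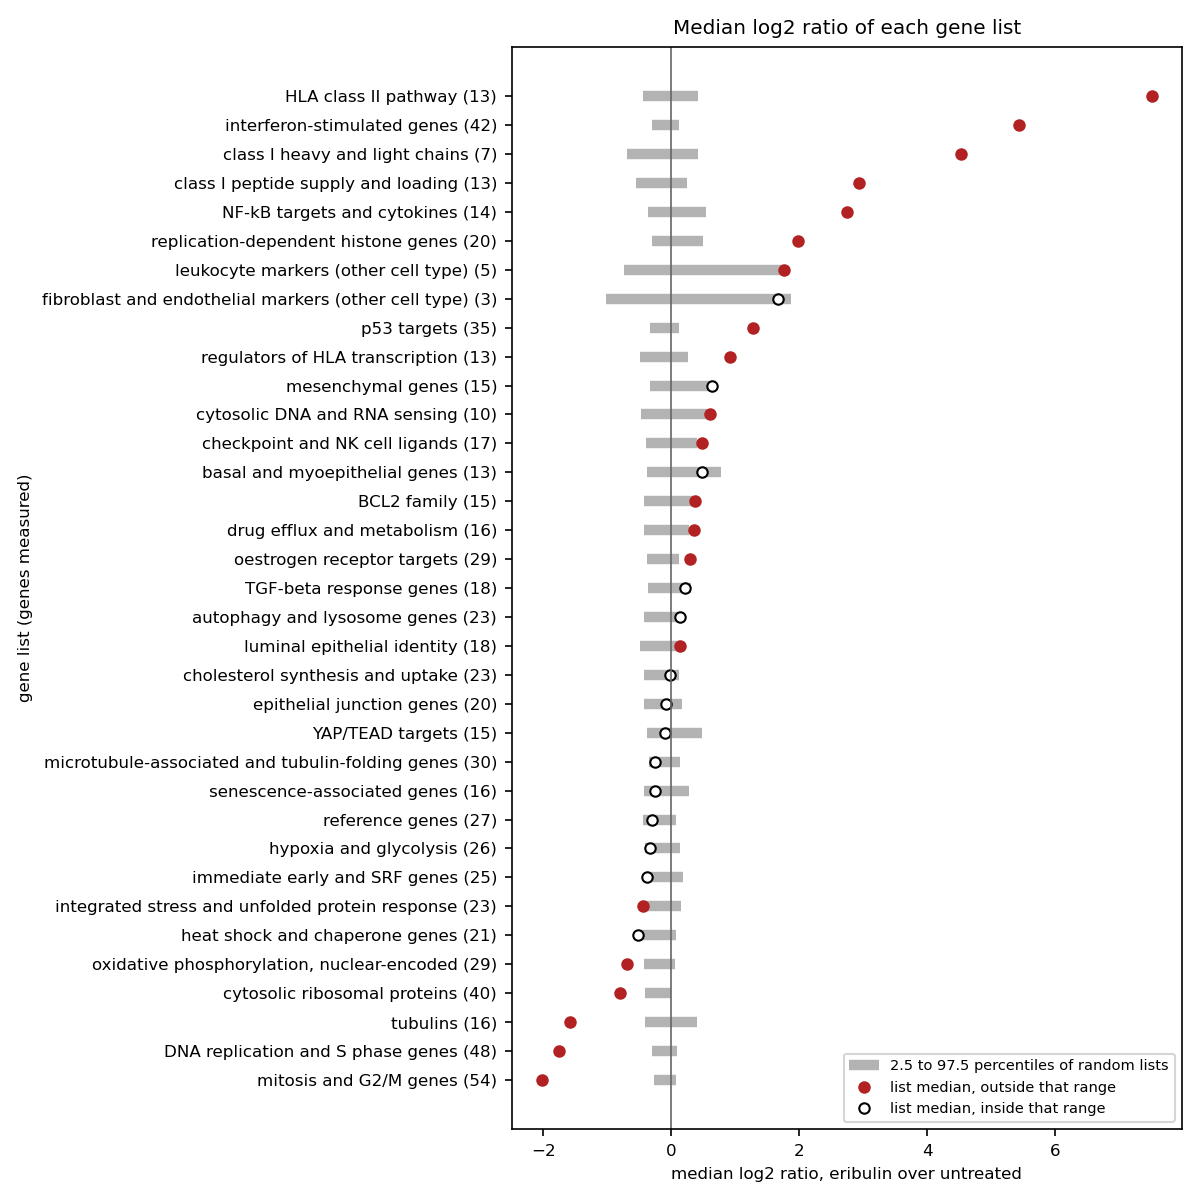
Median log2 ratio (eribulin over untreated, x axis) of the measured genes in each of the 35 gene lists (y axis, number of genes in brackets), with grey bars for the central 95% of 10000 random lists matched on expression. Filled red points lie outside their bar: the HLA class II list is highest at 7.50 and the list of mitosis and G2/M genes lowest at -2.01.

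All 7 genes of the class I heavy and light chain list were higher in the eribulin library, with a median log2 ratio of 4.52 (percentile 100), or 4.47 with HLA-G at its bound. HLA-A (ENSG00000206503) had 358 reads in the untreated library and 8729 in the eribulin library (interval of the fold 19.96 to 24.7). HLA-B (ENSG00000234745) had 30 and 8824 (187 to 397), and HLA-C (ENSG00000204525) had 52 and 6391 (85.2 to 149.9). The non-classical HLA-E was 11.1-fold higher (10.5 to 11.7) and HLA-F 49.7-fold (34.9 to 73.3). B2M, the light chain that all class I molecules share, was 12.1-fold higher (11.5 to 12.7). HLA-G had 0 and 23 reads, at least 6.98-fold higher against a floor of 3 counts in the untreated library. The HLA heavy chain genes are related in sequence, and reads can be divided among them in counting, so their single values are uncertain.

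The machinery that cuts, transports and loads class I peptides showed 10 of 13 genes higher, none lower and 3 neither, with a median of 2.93 (percentile 100). TAP1, a subunit of the peptide transporter, was 59.8-fold higher (52.5 to 68.5). The immunoproteasome subunit genes PSMB9, PSMB8 and PSMB10 were 1052-fold (291 to 8692), 579.7-fold (104 to 22932) and 7.64-fold (6.95 to 8.41) higher, with 2, 1 and 480 reads in the untreated library. TAPBP, which encodes tapasin, was 5.69-fold higher (5.32 to 6.10), and ERAP2, a peptide-trimming enzyme, 76.4-fold (20.8 to 636). TAP2, the partner of TAP1, appeared in the table only as a pair of suffixed entries outside the list, of which 1 was 18.6-fold higher (16.4 to 21.2) and the other had 0 reads in both libraries. The general endoplasmic reticulum chaperones CALR, CANX and PDIA3 had log2 ratios of -0.24, 0.03 and 0.18.

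Among regulators of HLA transcription 6 of 13 genes were higher, 0 lower and 7 neither (median 0.92, percentile 100). Besides NLRC5 these included CIITA, the activator of class II genes, at 313-fold (152 to 780.1), IRF1 at 60.7-fold (48.5 to 76.9) and STAT1 at 25.1-fold (23.6 to 26.8). The promoter-binding genes NFYA, NFYB and NFYC had log2 ratios of -0.10, 0.34 and -0.24. All 13 genes of the class II pathway were higher, with a median of 7.50 (percentile 100), or 6.84 with the 6 genes without untreated reads at their bound. CD74, the class II invariant chain, had 3 untreated and 17935 eribulin reads (5440.4-fold, interval 1861 to 26383), and HLA-DRA had 1 and 2905 (2644-fold, 474 to 104452). HLA-DPA1 and HLA-DPB1 had no untreated reads and were at least 469.9-fold and 223-fold higher, against 3 counts in that library.

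**Figure D2:**
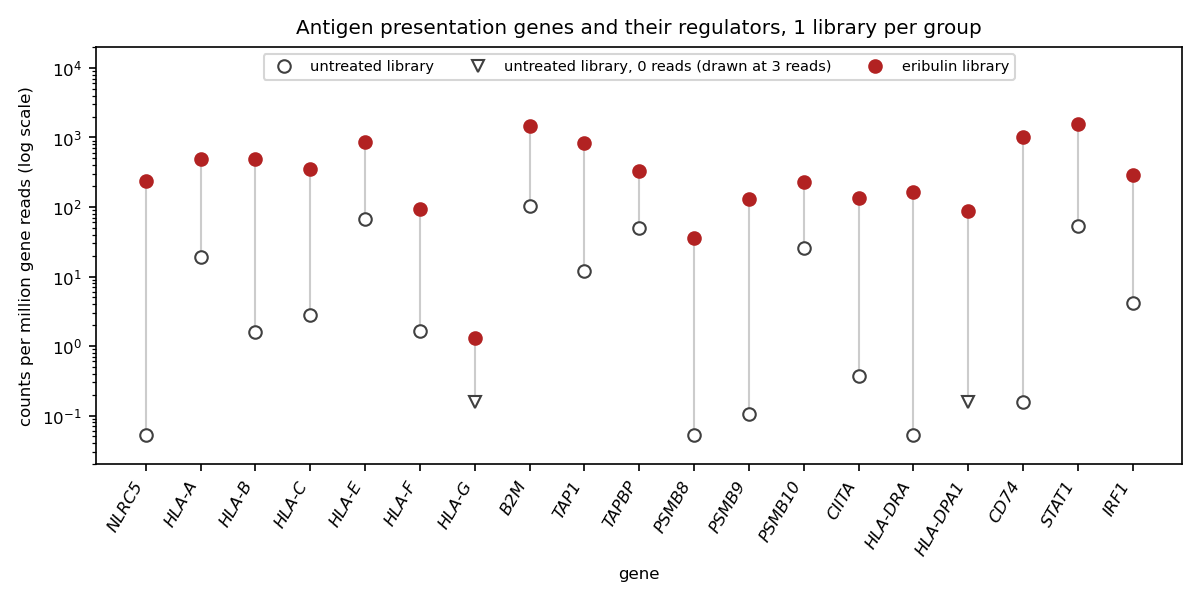
CPM of gene reads (y axis, log scale) of antigen presentation genes and their regulators (x axis) in the untreated library (open symbols) and the eribulin library (filled circles), with 1 library per group and no error bars. Each gene lies higher in the eribulin library, NLRC5 at 0.0531 and 235 CPM, and triangles mark genes without untreated reads, drawn at the level of 3 reads.

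Of 42 interferon-stimulated genes 41 were higher, none was lower and IFITM2 was neither (median 5.43, percentile 100). IFI44L, TRIM22 and XAF1 were among the 12 genes with the highest interval bounds. IFI44L and TRIM22 had no untreated reads and 2903 and 1788 eribulin reads, at least 881-fold and 542-fold higher against 3 counts in the untreated library. XAF1 had 1 and 3671 reads (3341-fold, 599 to 131985). GBP1, a guanylate-binding protein, was 918-fold higher (421 to 2502). Of 25 NF-kB target and cytokine genes with an entry, 14 reached the expression minimum, with 10 higher and 4 neither (median 2.75, percentile 100). The higher ones included CCL5 at 67.8-fold (18.4 to 565), BIRC3 at 23.0-fold (13.2 to 43.6) and ICAM1 at 11.1-fold (8.28 to 15.3). Their untreated reads were 2, 13 and 48. The 4 neither were NFKBIA, NFKB1, NFKB2 and SOD2, with log2 ratios of 0.62, 0.22, -0.03 and 0.18. Of 13 genes of cytosolic DNA and RNA sensing 10 reached the expression minimum, with 4 higher, 1 lower and 5 neither (median 0.61, percentile 98.2). Those below it were TMEM173 (7 untreated and 10 eribulin reads), IFI16 (0 and 1) and AIM2 (0 and 2). Among the higher genes ZBP1 had 1 and 69 reads and TLR3 had 0 and 20. The dsRNA-activated kinase gene EIF2AK2 was 2.55-fold higher (2.38 to 2.74), and the log2 ratio of MB21D1, which encodes the DNA sensor cGAS, was -1.26. Of 17 checkpoint and NK cell ligands 7 were higher, 2 lower and 8 neither (median 0.48, percentile 99.2). CD274, which encodes PD-L1, was 11.3-fold higher (9.02 to 14.2) and TNFSF10, the death ligand TRAIL, 27.0-fold (19.1 to 39.4), while the NKG2D ligand genes went both ways, with ULBP1 and MICB lower (log2 ratios -1.32 and -1.07), ULBP3 higher (2.86-fold, 1.18 to 7.93) and MICA and ULBP2 neither.

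Markers of other cell types were measured beside these immune genes. Only 5 of 18 leukocyte markers reached the expression minimum, 3 higher, 1 lower and 1 neither (median 1.77, percentile 97.6). LAPTM5 had 2 untreated and 37 eribulin reads, CD4 had 1 and 22, ITGAM had 6 and 25, and CORO1A had 257 and 121. CD8A, the one that was neither, had 152 and 186. PTPRC, the pan-leukocyte marker CD45, had 0 and 1. Of the fibroblast and endothelial markers 3 were measured, 2 higher and 1 neither (median 1.68, percentile 96.2), with 17 and 62 reads for COL3A1 and 6 and 26 for VWF.

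Cell cycle genes were lower in the eribulin library. Of 54 mitosis and G2/M genes 50 were lower, 0 higher and 4 neither (median -2.01, percentile 0). UBE2C, an enzyme of the anaphase-promoting complex pathway, was 16.8-fold lower (14.9 to 19.0), CDK1 10.7-fold (9.39 to 12.2) and AURKB 9.17-fold (8.12 to 10.4). CCNB1, encoding cyclin B1, was 2.73-fold lower (2.59 to 2.88) and the proliferation marker MKI67 2.99-fold (2.82 to 3.17). Of 48 DNA replication and S phase genes 47 were lower and 1 neither (median -1.76, percentile 0), including CDC45 at 7.57-fold (6.35 to 9.08) and RRM2 at 7.03-fold (6.59 to 7.50). Replication-dependent histone genes went the other way, with 15 of 20 higher, 1 lower and 4 neither (median 1.97, percentile 100). HIST1H4H was 8.79-fold higher (6.72 to 11.7), whereas HIST2H2AC was 6.67-fold lower (3.84 to 12.4). Most histone transcripts lack a poly(A) tail, and the libraries were made with an mRNA kit, so these values cover only the part captured.

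Targets of p53 were higher as a group, 22 of 35, with none lower and 13 neither (median 1.27, percentile 100). CDKN1A, the cyclin-dependent kinase inhibitor p21, had 1943 untreated and 9483 eribulin reads (4.44-fold, 4.23 to 4.67). MDM2, which targets p53 for degradation, was 3.08-fold higher (2.97 to 3.19), GDF15 6.77-fold (5.88 to 7.82) and FAS, a death receptor gene, 8.08-fold (6.45 to 10.2). TP53 itself had a log2 ratio of -0.49. In the BCL2 family 1 of 15 genes was higher, BBC3 (PUMA) at 3.33-fold (2.81 to 3.96), and 14 were neither (median 0.37, percentile 98.2). Of 16 senescence-associated genes 4 were higher, 4 lower and 8 neither (median -0.26, percentile 15.3). This list was not sorted by the direction a gene takes in senescence, so its median and counts cannot show or deny a senescent state. SERPINE1 was 15.5-fold higher (6.87 to 43.1), and HMGB2 was 4.98-fold lower (4.58 to 5.43).

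The tubulin list held alpha and beta tubulins, the building blocks of microtubules, and also gamma, delta and epsilon tubulins. Of its 16 measured genes 10 were lower, 0 higher and 6 neither (median -1.58, percentile 0). The gamma tubulin gene TUBG1 was lower, and the 6 neither were TUBG2, TUBD1, TUBE1, TUBA1A, TUBA8 and TUBB1. TUBA1B was 5.84-fold lower (5.70 to 5.98), TUBB 5.33-fold (5.19 to 5.47), TUBB4B 4.64-fold (4.49 to 4.79), TUBB2A 3.82-fold (3.15 to 4.66) and TUBA1C 3.48-fold (3.34 to 3.63). TUBB3 was present only under suffixed names, its more abundant entry being 5.20-fold lower (4.54 to 5.97), while the other, with 32 and 66 reads, had a log2 ratio of 0.89 (1.88-fold, 1.21 to 2.96). Microtubule-associated and tubulin-folding genes showed 1 of 30 higher, 3 lower and 26 neither (median -0.25, percentile 12.3). STMN1, encoding the tubulin-binding protein stathmin, was 5.02-fold lower (4.70 to 5.35) and MAP1B 6.46-fold higher (3.32 to 14.1). Tubulin genes have near-identical copies and pseudogenes, so the single values are uncertain.

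**Figure D3:**
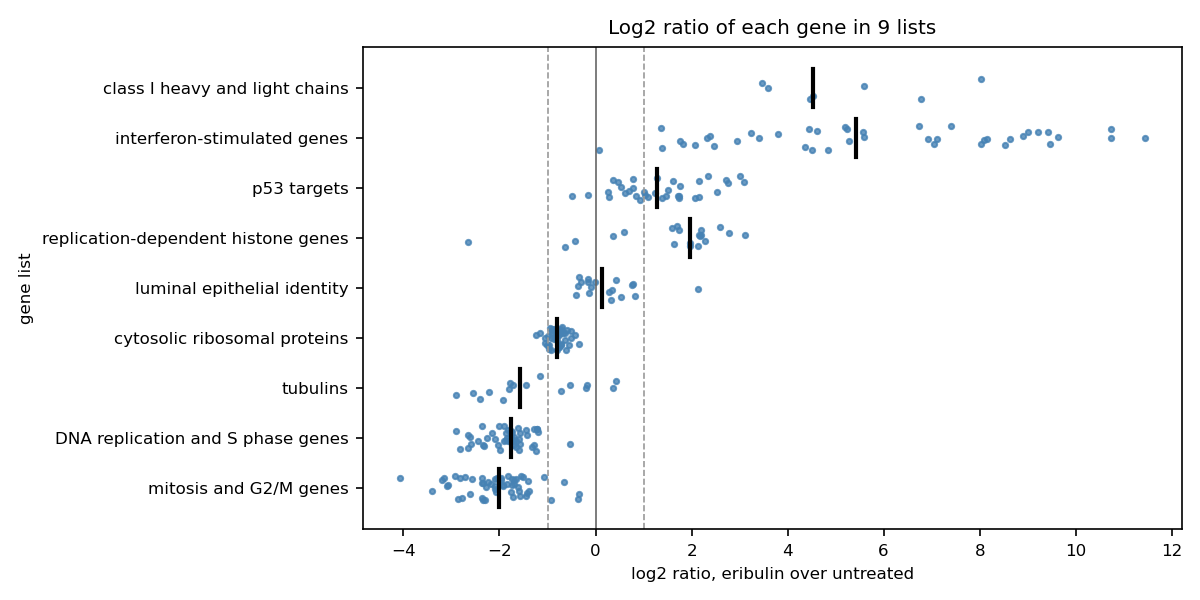
Log2 ratio (eribulin over untreated, x axis) of each measured gene (points) in 9 gene lists (y axis), with black bars for the list medians and dashed lines at the 2-fold rule. All mitosis and replication genes lie below 0, all class I genes lie above 3, and luminal genes lie around a median of 0.14.

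Of 18 luminal genes 1 was higher and 17 neither (median 0.14, percentile 97.8). ESR1, the oestrogen receptor gene, had 5588 and 6074 reads and a log2 ratio of -0.02, a value above 0 when scaled by total counts or upper quartile. Of 29 oestrogen receptor targets 3 were higher, 2 lower and 24 neither (median 0.29, percentile 99.9), with SERPINA1 8.54-fold higher (4.81 to 16.5) and MYBL1 2.30-fold lower (2.03 to 2.62). Basal and myoepithelial genes showed 4 of 13 higher and 9 neither (median 0.48, percentile 86.2), among them ACTA2 at 8.21-fold (6.02 to 11.4). Epithelial junction genes showed 1 of 20 higher and 19 neither (median -0.09, percentile 59.4), and CLDN1 was the higher one at 17.0-fold (9.93 to 31.5). Of 15 mesenchymal genes 5 were higher, 3 lower and 7 neither (median 0.64, percentile 95.9), with COL5A2 at 4.55-fold higher (2.64 to 8.34) and TWIST1 at 2.73-fold lower (1.72 to 4.44). TGF-beta response genes gave 4 higher, 1 lower and 13 neither of 18 (median 0.21, percentile 91.6). YAP/TEAD targets gave 1 higher, 3 lower and 11 neither of 15 (median -0.10, percentile 26.1), including CYR61 at 3.68-fold lower (3.09 to 4.39). The junction and YAP/TEAD medians turned positive, 0.12 and 0.11, with scaling by total counts.

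Several stress and growth factor response genes were lower. Of 25 immediate early and SRF genes 1 was higher, 7 lower and 17 neither (median -0.38, percentile 2.84). FOSB was 29.6-fold lower (22.0 to 40.8), FOS 14.3-fold (12.8 to 15.9) and EGR1 5.26-fold (4.60 to 6.03). In the integrated stress and unfolded protein response list 1 of 23 genes was higher, 6 lower and 16 neither (median -0.44, percentile 1.69). The lower ones included the serine synthesis genes PHGDH and PSAT1 at 4.62-fold (4.30 to 4.97) and 3.11-fold (2.76 to 3.50), and asparagine synthetase, ASNS, at 2.53-fold (2.33 to 2.74). Heat shock and chaperone genes showed 0 of 21 higher, 2 lower and 19 neither (median -0.52, percentile 2.68), with HSPE1 2.51-fold lower (2.42 to 2.61).

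Cytosolic ribosomal protein genes lay below 0 in all 40 cases, but by small amounts, with 5 lower by the rule and 35 neither (median -0.80, percentile 0). RPL14 was 2.35-fold lower (2.30 to 2.41). Nuclear-encoded oxidative phosphorylation genes showed 5 of 29 lower, 0 higher and 24 neither (median -0.69, percentile 0), including COX6C at 2.05-fold (2.00 to 2.10). Of 26 hypoxia and glycolysis genes none passed the rule (median -0.32, percentile 9.37). Cholesterol synthesis and uptake genes gave 1 lower, EBP at 2.24-fold (2.08 to 2.42), and 22 neither of 23 (median -0.01, percentile 83.9), a median above 0 when scaled by total counts or upper quartile. Autophagy and lysosome genes gave 3 higher and 20 neither of 23 (median 0.14, percentile 97.2), with CTSD, cathepsin D, 2.21-fold higher (2.15 to 2.28). Drug efflux and metabolism genes gave 3 higher and 13 neither of 16 (median 0.36, percentile 99.2), the transporter gene ABCC3 being 5.18-fold higher (4.44 to 6.06). Reference genes often used for scaling gave 2 lower, HPRT1 and PPIA, and 25 neither of 27 (median -0.30, percentile 18.2), and GAPDH was 1.69-fold lower (1.68 to 1.71).

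The 12 genes named for high interval bounds, by a rule that passed over GBP1 and GBP4, also held RARRES3, a retinoid-inducible growth suppressor gene, and LGALS17A, both without untreated reads, at least 749.9-fold and 682-fold higher against 3 counts in that library. APOL6, of the apolipoprotein L family, had 1 and 3630 reads (3303-fold, 593 to 130511), and IFIT3 was 845-fold higher (329.6 to 3102). Among the 12 genes named for low bounds 9 had no eribulin reads, and most were loci with clone names. RP11-161H23.5 (ENSG00000258232) had 1433 untreated reads and was at least 525-fold lower against 3 counts in the eribulin library. CFHR4, a complement factor H-related gene, had 173 and was at least 63.4-fold lower, but its untreated RPKM was 0.0180, so few of these reads entered the RPKM and what they are is not known. FAM72C had 230 and 1 (253-fold lower, 44.9 to 10026), while its near-identical copies FAM72A, FAM72B and FAM72D were 6.18-fold, 5.23-fold and 4.40-fold lower. Several of these loci have close copies, and whether counting used the strand was not given in the sources used here, so reads of copies or antisense partners may not be separated.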

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

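With 1 library per group, no replicate could be left out, no other split of the libraries exists, and no paired analysis was possible because each group held 1 library. Lists matched on length and GC content and lists with suffixed rows were chosen after seeing the data. The counts of higher and lower genes stayed within 1.5 times the main counts, 2093 and 1322, under the other scalings, priors, the RPKM ratio and no filter. For the RPKM ratio genes were called on the size of the ratio alone, without an interval. The counts were 711 and 815 with a minimum of 10 CPM, which tests fewer genes and leaves lower genes in the majority. They were 3291 and 2936 at 1.5-fold, and 771 and 306 at 4-fold. The NLRC5 log2 ratio of 10.94 was 9.38 with a prior count of 5 and 7.35 as an RPKM ratio with 0.1 added, both additions being large against its untreated value. The class I heavy and light chains median log2 ratio of 4.52 was 5.03 at the minimum of 10 CPM, which drops HLA-G, and 5.62 with a prior count of 0.25, which moves the fitted value of HLA-G. The luminal median turned to -0.0157 without a filter, which adds a low gene, and the leukocyte marker median to -0.53 at 10 CPM, which leaves few markers. The other list medians outside the random range kept their sign, and no named gene past the rule reversed, although 209 of 1245 alternative values lay outside the gene's counting interval. Random lists not matched on expression put BCL2 family, oestrogen receptor, luminal and drug efflux lists inside the range (93.7, 95.7, 75.1 and 94.5) and 5 others outside it. With length and GC matched by principal transcript, the leukocyte list fell inside (96.7). With merged exon length the stress response list did too (5.24), as did the luminal list. For the histone list this matching was not used, since 65% of its genes had a length, and those lay at percentile 100. With suffixed rows, class I peptide supply had 11 of 14 genes higher (median 3.09) and tubulins 11 of 17 lower (-1.71). Depth limits genes with a few reads, whose intervals span several-fold.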

Other observations

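The gene families and single genes in the next paragraphs were chosen after their values were seen. Guanylate-binding proteins, GTPases that act against intracellular pathogens, were higher in all 6 measured cases (median log2 ratio 6.72), with GBP4 at 1 untreated and 2082 eribulin reads. All 5 apolipoprotein L genes (median 9.01) and all 3 butyrophilin 3A genes (7.39) were higher, APOL3 with 2 and 2257 reads and BTN3A2, from a family read by gamma-delta T cells, 222-fold higher (94.9 to 685). Of 9 complement entries, with CFB counted under a pair of suffixed names, 8 were higher (median 3.92), including C1R at 32.5-fold (18.4 to 63.3), C3 at 16.0-fold (9.67 to 28.3) and SERPING1, which had no untreated reads and 462 eribulin reads, at least 140.1-fold higher against 3 counts. These complement entries were picked by hand and leave out other complement genes, so their share does not speak for the pathway. C4A and C4B are near-identical copies, so their single values are uncertain. WARS, tryptophanyl-tRNA synthetase, had 1827 and 55560 reads (27.7-fold, 26.4 to 29.01), and the tryptophan-degrading enzyme gene IDO1 had 0 and 1086, at least 329-fold higher against 3 counts. Among 12 caspase genes 6 were higher, among them CASP4 at 7.81-fold (5.99 to 10.3), and CASP2 and CASP6 had log2 ratios of -0.84 and -0.83.

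Of 74 mitochondrial ribosomal protein genes 9 were lower, none higher and 65 neither, and 73 lay below 0 (median -0.63), or 67 when scaled by total counts. None of 13 mitochondrially encoded protein genes passed the rule, and all lay below 0 with TMM (median -0.64, from -0.78 for MT-ND2 to -0.10 for MT-ND5), and 11 of 13 when scaled by total counts. Neither family was set against random lists. Long intergenic RNAs split 239 higher to 53 lower of 770, against 1363 to 1043 of 13089 protein-coding genes, a contrast not adjusted for expression. Across 5 classes of rising expression the median log2 ratio of all genes with a known length went from 0.53 to -0.18. KLF2, a transcription factor gene, was 22.3-fold lower (15.2 to 34.2). Some loci with close copies had reads almost only in 1 library: CSPG4P9 had 92 and 0 reads and CSPG4P10 0 and 39. The symbol PIK3R2 stood for a pair of Ensembl identifiers. Of these ENSG00000268173 had 5 and 1878 reads and ENSG00000105647 had 2386 and 2255, and what sets them apart was not examined.

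Of the tests below, those of leukocytes, of library scaling, of an unnamed interferon exposure, of length and GC content, and of summed tubulin reads were chosen after the result was seen. The comparison of tubulin reads was planned. A planned count of ribosomal protein genes below 0 under each scaling was set aside, since the shifts between scalings were too small for it to come out otherwise.

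The block of interferon-responsive and HLA genes was weighed first. Leukocytes in the treated sample are argued against by a median of 2 reads over 18 leukocyte markers and 1 read of PTPRC, where CD74 had 17935. Of the 18 markers 10 had at most 3 eribulin reads. The most abundant, CD8A, had 186, but also 152 in the untreated library, and LAPTM5, ITGAM and CD4 had 37, 25 and 22 eribulin reads. Library scaling moves all genes alike, so it cannot set a list apart from genes of matched expression. It is argued against by percentile 100 of the interferon-stimulated list, which repeats the list result above. An interferon exposure that the labels do not name cannot be told apart from a response of the cells to eribulin, since it would fall on the same single library: CIITA, IDO1 and CXCL9, which respond to interferon gamma, had at least 517 reads each, IFNG, IFNB1 and the IFNA genes had 0, and the 22 interferon genes together held 18 reads, all of lambda type. A drug-induced release of interferon, or signalling without it, may account for the block and was not tested.

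The second pattern was the small shortfall of ribosomal protein and respiratory chain genes. Library scaling as the whole cause is argued against, since both lists lay at percentile 0 of random lists of matched expression, which repeats the list results above. Even so, 2 of 29 respiratory chain genes lay above 0, and 5 when scaled by total counts. For transcript length and GC content, the ribosomal list lay at percentile 0.04 and the respiratory list at 0.12 of random lists matched on expression, length and GC content. The bins were coarse and small ones were merged, so differences within a bin remain and these percentiles cannot decide on length and GC content. The central 95% of the matched lists had medians from -0.67 to -0.39 for the ribosomal list, whose median was -0.80. Genes of respiratory chain and mitochondrial ribosomal families, which were also low, stayed in the pool of these random lists. Whether part of the shortfall goes with short, abundant transcripts therefore cannot be told from this range. An effect of eribulin on growth stays open and was not tested.

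The third pattern was the lower level of tubulin genes. Reads moved between near-identical copies are argued against, since the reads summed over 56 alpha and beta tubulin genes and pseudogenes were 110554 untreated and 25175 eribulin, a log2 ratio of -2.27. Free tubulin is known to trigger decay of tubulin mRNA, and loss of tubulin RNA after transcription may be a candidate explanation, as may lower transcription in less proliferative cells. The test compared reads behind the RPKM with the remaining gene reads, and its median difference was -0.46 over only 4 genes that ran from -1.21 to 2.41. The highest was TUBA1A, with 23 untreated and 2 eribulin remaining reads, while TUBA1C, TUBB and TUBB6 lay at -0.86, -0.06 and -1.21. Over all kept genes that could be used the median difference was -0.16. By the rule written beforehand a tubulin median above -0.5 would have favoured lower transcription. A requirement of at least 6 genes was added after the value was seen, so loss after transcription and lower transcription are held not to be told apart. Whether the remaining reads come from introns is not known.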
